A study of Mus musculus with 12 samples.

How the data were processed

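RNA sequencing was carried out on hair follicle cells sorted from the skin of K15-EGFP transgenic mice, in which a promoter fragment of the keratin 15 gene drives a green fluorescent protein in hair follicle stem cells. Per the labels' protocols, the sort kept cells with high reporter signal and high integrin alpha 6 that lacked Sca-1, a gate meant to hold bulge stem cells and hair germ cells and to leave out the upper follicle and epidermis, where Sca-1 is made. The 12 libraries fell into 4 groups of 3: young and old mice, each in telogen, the resting stage of the hair cycle, and in early anagen, the start of hair growth, which was brought on by depilation. The labels do not say whether the 3 samples of a group came from separate mice, so p-values measure the spread between these samples only, part of which may be technical. RNA was purified on micro columns and total RNA was converted with a stranded SMARTer kit, per the labels' protocols.

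The submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and the mouse genome build GRCm39. The setting for strand during counting is not given in the sources used here, so overlapping and antisense genes may share reads. The deposited table held 55359 genes with Ensembl identifiers, symbols, GRCm39 coordinates and exonic lengths. For each library it gave raw read counts per gene, deposited without normalization, and FPKM computed by the authors. Each deposited FPKM value equalled the count divided by the exonic length in kilobases and by the library's total count, scaled to FPKM, within 0.005. No gene annotation of that build other than the table itself was used here.

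The columns of the table were matched to samples by age and replicate number, which both appear in the column names. The stage is written there as pk or nonpk. The columns marked nonpk were taken as untreated telogen and those marked pk as depilated early anagen, because depilation is the only treatment the labels name, and this reading is an inference from the labels. The direction of every telogen to early anagen difference rests on it.

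The tests, gene lists, rule for naming genes and alternatives were fixed before the data were examined. The plan named limma on log2(FPKM + 1), with edgeR on counts to take its place if the table held raw counts, which it did. Genes were kept with filterByExpr, which left 16011 of 55359. The 39348 genes not kept included Ly6a, which encodes Sca-1, and Cdkn2a. Libraries were scaled with TMM factors, and edgeR's quasi-likelihood test (edgeR 4.0.16 and limma 3.58.1 in R 4.3.3) was fitted to all 12 libraries with 1 mean per group, no block and no covariate. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes kept, and the threshold was an adjusted p of 0.05. The 5 comparisons were early anagen against telogen in young and in old, old against young in telogen and in early anagen, and the difference between the ages in the early anagen response (old response minus young response, an interaction term). The standard error (SE) of a log2 fold change is its absolute value divided by the square root of F. Levels are given as CPM, a library-size-normalized count, scaled with the TMM factors, as mean ± SD over n = 3 libraries. Every adjusted p given for a gene comes from the edgeR test unless another tool is named.

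The table of 27 gene lists was written from textbook knowledge of hair follicle compartments, signalling pathways, ageing and other skin cell types. Of these, 26 had at least 4 genes kept and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 26 lists, then again with a correlation estimated for each list. The fry test, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, was also run. For each list, the number of genes past the threshold is given from the adjustment over all genes and, as "adjusted over the list alone", from an adjustment within the list.

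Genes named in the text follow a fixed rule. For each comparison they are the 5 genes with the largest and the 5 with the smallest log2 fold change among protein-coding, named genes past the threshold whose groups do not overlap and whose mean FPKM is at least 5 in the higher group. To these are added up to 4 genes per list with the largest absolute change among those past the threshold, and a fixed set reported in every comparison: Kitl, Krt15, Itga6, Ly6a, Cd34, Lgr5, Shh, Mki67, Cdkn1a, Cdkn2a, Trp53, Ptgs2, Edn1, Tgfb2, Col17a1 and Wnt10b. Any other gene named is said to be chosen after its values were seen. For a gene without counts in 1 group, the fold is given as a lower bound against a floor of 3 counts over the group, 0.124 to 0.128 CPM. For a gene with 1 to 3 counts in a group, the ratio is given with its exact 95% counting interval. Such intervals and floors cover counting error only, because the libraries carried no molecular identifiers. Genes whose reads can be shared with near-identical copies, such as Gapdh, Eno1, ribosomal protein genes and histone genes, have uncertain values.

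Total counts per library lay between 7291178 and 8478442. On simulated counts drawn from these libraries' means and dispersions, with 200 genes changed, the test recovered 33% of 2-fold and 80% of 4-fold changes in the young response (15415 genes) and 30% and 77% in the old response (15406 genes). The shares were 29% and 80% for age in telogen (15415 genes), 26% and 79% for age in early anagen (15406 genes), and 10% and 54% for the interaction (15415 genes).

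Alternatives were no filter, a mean FPKM of at least 5, DESeq2 1.42.0, DESeq2 size factors in edgeR, removal of mitochondrial, ribosomal protein and haemoglobin genes, a replicate block, only the groups compared, a 2-fold minimum, and each library left out in turn. Others were limma on log2(FPKM + 1), on log2(FPKM + 0.1), with quantile normalization, with median-of-ratios factors and with array weights. Leaving out the telogen library numbered 1 of both ages was added after the data were seen. A set of 1117 gene ontology terms from the deposited table was also tested with camera after the data were seen. The rerun tables and figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.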

Results

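Transcriptomes were measured in 12 libraries of sorted hair follicle stem cells and hair germ cells, with 3 libraries each from young telogen, young early anagen, old telogen and old early anagen skin. Library totals ran from 7291178 to 8478442 counts, and 16011 genes had enough counts to be tested. The gate was visible in the values of the genes used for the sort. Krt15, whose promoter drives the reporter used for the sort, stood at 6042 ± 1140 CPM in young telogen and 8032 ± 1497 CPM in old telogen (SD, n = 3), and at 2329 ± 337 and 2903 ± 331 CPM in young and old early anagen. Itga6, which encodes the sorted integrin, lay between 291 ± 51 and 392.1 ± 28 CPM in the 4 groups and passed the test in none of the 5 comparisons. Ly6a, the gene of Sca-1, which the sort excluded, did not exceed 1.66 CPM in any library, and Cdkn2a, a senescence-associated cell cycle inhibitor, did not exceed 0.881 CPM, so neither was tested. Genes used for the sort are no finding between groups.

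Markers of other cells differed in level between lists. The immune list summed to between 66.8 ± 7.9 and 78.3 ± 26 CPM in the 4 groups, and the red blood cell list to between 0.296 ± 0.26 and 1.79 ± 1.6 CPM. The fibroblast and dermal papilla list summed to between 252 ± 30 CPM in old early anagen and 545 ± 167 CPM in old telogen. The vessel list summed to between 332 ± 21 CPM in young telogen and 590 ± 77 CPM in old telogen, of which Cspg4, which is not confined to vessels, made up 330 ± 21 and 578 ± 77 CPM. No fixed immune, nerve or melanocyte list passed camera in any comparison. Of the melanocyte list, Mitf carried most of the signal, at 122 ± 16 CPM in young telogen. The upper follicle and sebaceous gland list, by contrast, summed to 6382 ± 1488 CPM in young telogen and 4070 ± 1664 CPM in old telogen, with Krt79, a keratin of the infundibulum, at 2567 ± 1181 and 1762 ± 1085 CPM. The epidermal differentiation list summed to between 3202 ± 1110 CPM in young early anagen and 5475 ± 1339 CPM in old telogen. The gate was meant to leave out both the upper follicle and the epidermis. Mitochondrial ribosomal RNA took 7.52% to 12.3% of the counts of a library.

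The first principal component carried 36.2% of the variance and separated telogen from early anagen libraries. The second carried 11.1%, and old telogen replicate 1 lay apart on it, at -89.8 against -2.97 and -22.0 for the other old telogen libraries. Correlations between libraries of the same group, across genes, which are not independent replicates, were 0.905 to 0.948.

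**Figure D1:**
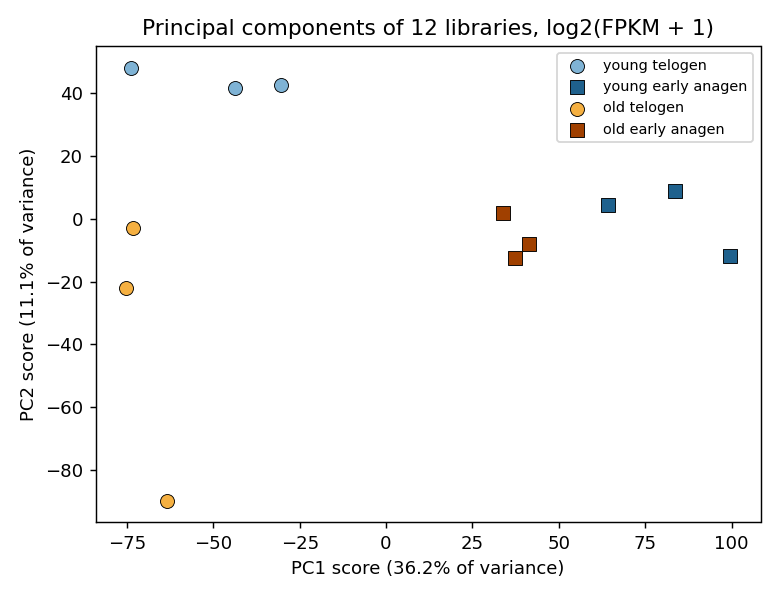
Scores of the 12 libraries on the first (36.2% of variance, x axis) and second (11.1%, y axis) principal components of log2 CPM. Values of the tested genes were scaled with the TMM factors, and each library is 1 point, with colour and shape by group. The title inside the figure names log2(FPKM + 1), which was not the measure used. Telogen libraries lie at negative and early anagen libraries at positive scores on the first component, and old telogen replicate 1 lies lowest on the second, at -89.8.

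The first question was how early anagen after depilation differed from untreated telogen in these cells of young mice. At both ages, every early anagen library came from depilated skin, so hair growth cannot be told apart from other effects of depilation. Mki67 and the hedgehog genes Ptch1 and Shh rose, as did Kitl, while Cd34 and Col17a1 fell. Mki67, which marks dividing cells, went from 342 ± 241 to 2197 ± 165 CPM (log2 fold change 2.68, SE 0.45, adjusted p = 0.00031), with every early anagen library above every telogen library. Ptch1, the hedgehog receptor and a direct target of the pathway (ENSMUSG00000021466, GRCm39 chromosome 13, 63656142 to 63721412), went from 123 ± 16 to 1014 ± 182 CPM (3.05, SE 0.15, adjusted p = 3.1e-09). Shh, the hedgehog ligand made by the growing hair germ, was 144 times higher (95% counting interval 39.6 to 1199), from 2 counts over the 3 telogen libraries. Cd34, a surface marker of the bulge, fell by 2.71 (SE 0.28, adjusted p = 4.1e-06) and Col17a1, a hemidesmosome collagen of follicle stem cells, fell by 1.40 (SE 0.14, adjusted p = 2.4e-06). Kitl, which encodes stem cell factor, the ligand on which melanocyte stem cells depend (ENSMUSG00000019966, GRCm39 chromosome 10, 99851492 to 99936278), went from 25.6 ± 1.4 to 129 ± 34 CPM (2.33, SE 0.27, adjusted p = 1e-05).

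In total 4003 genes passed the test in young, 2010 higher and 1993 lower in early anagen, and 3852 of them had groups that did not overlap, which chance gives to 10% of genes that no test has selected. Among the steepest increases by the naming rule were those of Ckb, a brain-type creatine kinase (6.40, SE 1.11), the histone gene H2bu2, Chst2, a sulfotransferase (6.08, SE 0.54), and Col27a1, a fibrillar collagen (5.85, SE 0.53). The H2bu2 ratio was 93.2 (95% counting interval 31.6 to 455), and its reads may be shared with other histone genes. The steepest decreases were in Fgf18, a growth factor of the resting bulge (-6.62, SE 1.36), Sncg, a synuclein (-5.81, SE 0.63), Best2, an anion channel (-4.87, SE 1.11), Angptl7 (-4.27, SE 0.87) and Myoc, which encodes myocilin (-4.07, SE 0.62).

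Among the fixed lists, 31 of 32 cell cycle genes rose and 0 fell, with a median log2 fold change of 2.86, and adjusted over the list alone all 32 rose. Ube2c (3.79), Aurkb (3.69) and Plk1 (3.50), all mitotic genes, were the steepest. Of 23 hair germ and early anagen progenitor genes, 12 rose and 1 fell (12 and 2 adjusted over the list alone), including Dlx2, a homeobox gene, at 4.15 (SE 0.55). Of 29 genes of DNA double-strand break repair, 14 rose and 1 fell (15 and 1 adjusted over the list alone). Rad54l (3.32), Brca1 (3.17) and H2ax (2.81), which were among them, are also made during DNA replication. In the Notch list, 8 of 18 genes fell and 1 rose (8 and 3 adjusted over the list alone), among them Dll1, a Notch ligand (-1.53), Notch3 (-1.52) and Dtx4 (-0.99). The last did not pass without young telogen replicate 1 or 2 or young early anagen replicate 2 or 3. Of 83 cytosolic ribosomal protein genes, 11 rose (4 adjusted over the list alone), with a median of 0.19 and uncertain values where copies share reads. These 5 lists passed camera at the preset correlation and none did with an estimated correlation. The adjusted p with an estimated correlation was 0.142 for cell cycle, 0.18 for the hair germ, repair and Notch lists and 0.788 for ribosomal proteins.

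Other lists held genes moving both ways in young. The bulge list had 7 of 22 genes lower and 3 higher (9 and 6 adjusted over the list alone), its median being -0.08, its mean -0.62 and its camera adjusted p 0.178. The steepest of its lower genes were Fgf18, Ccn2 (-2.90), Cd34 and Foxc1, a forkhead factor of stem cell quiescence (-1.40). In the melanocyte niche list 7 of 17 genes rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.0517). Besides Kitl they included Edn1 (5.29, SE 1.07) and Edn2 (4.25, SE 0.91), endothelins that act on melanocytes, and Fgf2, at 167 times the telogen level (95% counting interval 29.6 to 6643). Wnt genes rose in 8 of 29 cases and fell in 2 (9 and 2 adjusted over the list alone), such as Tcf7 (1.73) and Wnt7b (1.77). Of 33 BMP and TGF-beta genes, 5 rose and 7 fell (5 and 7 adjusted over the list alone), with Nog, a secreted BMP inhibitor, at -2.65 and Id2, a BMP target, at -2.18. That list's median was 0.02 where its mean was -0.06. Hemidesmosome and basement membrane genes split into 12 higher and 8 lower of 28 (12 and 9 adjusted over the list alone), with Fras1 (3.61) and Col4a1 (2.35) higher and Col17a1 lower. In the interferon and antigen presentation list 8 of 26 genes fell and 1 rose (8 and 1 adjusted over the list alone), with decreases in H2-K1 (-1.28), Tap2 (-1.42) and Nlrc5, their transactivator (-1.25). That list's median was -0.19, its mean 0.16 and its camera direction downward (adjusted p = 0.178).

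The remaining lists did not pass camera in young. In glycolysis and hypoxia 8 of 25 genes rose and 4 fell (8 and 7 adjusted over the list alone), with Ndrg1, a hypoxia-induced gene, at -2.88. Of the upper follicle and sebaceous list 3 of 23 rose and 5 fell (3 and 6 adjusted over the list alone), including Gata6, a transcription factor of the sebaceous duct (-2.28, SE 0.28), Acsbg1, an acyl-CoA synthetase (-2.07, SE 0.32), and Ly6d (-1.78, SE 0.21). Epidermal differentiation had 4 of 24 higher and 5 lower, p53 targets 5 of 28 in each direction and immediate early genes 2 of 24 higher and 8 lower, with Ccn1 at -1.63. Of senescence-associated secretory genes 3 of 18 rose and 2 fell (median -0.12, mean 0.31), and of prostaglandin genes 1 of 27 rose and 5 fell. Of 12 wound keratinocyte genes 2 fell and 0 rose, although the list's median was 0.90 and its mean 0.85. Of 8 hair shaft genes 3 rose. Fibroblast and dermal papilla genes had 4 of 11 higher, with Vcan, a proteoglycan, at 6.34 (SE 0.89), and 2 lower, their median of -0.59 lying below and their mean of 0.61 above 0. Of 12 mitochondrially encoded genes 5 fell, mt-Nd6 by 0.93 (SE 0.17), while the values of mt-Cytb (-0.45) and mt-Co1 (-0.54) turned to 0.01 and 0.02 under quantile normalization. Trp53 rose by 0.83 (SE 0.17, adjusted p = 0.0013). Cdkn1a, a p53 target that blocks the cell cycle, was at -1.07 (adjusted p = 0.046), but passed in only 7 of 13 alternatives and with 1 of 6 left-out libraries. Krt15, the gene of the sort reporter, was lower in early anagen (-1.38, SE 0.16, adjusted p = 1e-05), in all 3 libraries. Itga6 (-0.10), Lgr5 (0.23), Tgfb2 (-0.64), Ptgs2 (-0.65) and Wnt10b (2.23, SE 1.02) did not pass.

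In old mice Mki67 and Ptch1 rose and Cd34 fell, while Kitl did not pass. Mki67 went from 150 ± 76 to 1417 ± 83 CPM (3.24, SE 0.46, adjusted p = 0.00013). Ptch1 went from 127 ± 7.1 to 448 ± 30 CPM (1.82, SE 0.15, adjusted p = 1.1e-06), and Cd34 fell by 2.87 (SE 0.28, adjusted p = 7e-06). For all of these, no telogen library overlapped the early anagen libraries. Kitl was 37.7 ± 15 CPM in telogen and 63.2 ± 14 CPM in early anagen (0.75, SE 0.26, adjusted p = 0.061) and did not pass. Without old telogen replicate 1, at 53.6 CPM, its log2 fold change was 1.09 (adjusted p = 0.0078), and over 13 alternatives it passed in 4, with an adjusted p of 0.0065 to 0.095.

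A total of 2339 genes passed in old, 1321 higher and 1018 lower, and 2311 of them had groups that did not overlap, against 10% by chance among unselected genes. Without old early anagen replicate 1 or 2 the count was 1526 or 1550. The steepest increases by the naming rule included the histone gene H2ac8, at 220 times the telogen level (95% counting interval 39.0 to 8711, reads possibly shared between copies). Klk6, a kallikrein protease (6.92, SE 0.97), and Mtmr7, a lipid phosphatase (5.94, SE 0.75), were among them. So were Lcn2, a siderophore-binding protein of stressed epithelium (5.83, SE 1.18), and Dio2, which activates thyroid hormone (5.80, SE 0.61). The steepest decreases by that rule were in Galnt15 (-6.44, SE 0.98), Fzd9, a Wnt receptor (-5.18, SE 1.02), Angptl7 (-5.00, SE 0.92), Myoc (-4.52, SE 0.70) and Calr3 (-4.12, SE 0.78). Shh was at least 12-fold, Fgf2 at least 16.7-fold and Krt27, an inner root sheath keratin, at least 24.99-fold higher in early anagen than in telogen, where their counts were 0. The Shh call was lost without old telogen replicate 1, 2 or 3 or old early anagen replicate 3.

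All 32 cell cycle genes rose in old (32 adjusted over the list alone), with a median of 3.13 and Birc5 (4.99), Aurkb (4.49) and Ccnb1 (4.05) in the lead. Of the bulge list 10 of 22 fell and 0 rose (13 and 1 adjusted over the list alone), with Ccn2 at -3.06 and Wif1, a Wnt inhibitor, at -1.64. Lgr5, which belongs to it, fell by 0.91 (SE 0.19, adjusted p = 0.0039). Of the upper follicle and sebaceous list 11 of 23 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 1.19. They included Far2, a fatty acyl reductase (3.81, SE 0.53), Mc5r, the melanocortin receptor of sebocytes (2.94, SE 0.79), Pparg, the regulator of lipid synthesis (2.64, SE 0.66), and Elovl3 (4.55, SE 1.29). The Mc5r call was lost in 4 of 12 alternatives (adjusted p up to 0.22) and without old telogen replicate 2 or 3 or old early anagen replicate 3, the Elovl3 call without old telogen replicate 1 or 3 or old early anagen replicate 1, and the Pparg call without old telogen replicate 3. Of 33 BMP and TGF-beta genes 12 fell and 4 rose (13 and 4 adjusted over the list alone), with Smad9 (-3.06), Id2 (-2.56), Nog (-2.47) and Id3 (-2.41) the steepest. Nog opposes the pathway that Id2 and Id3 report. The repair list had 12 of 29 genes higher (15 adjusted over the list alone), such as Chek1 (3.09) and Brca1 (2.81). The hair germ list had 5 of 23 higher and 1 lower (5 and 1 adjusted over the list alone), among them Edar, the ectodysplasin receptor (3.64). Of 83 ribosomal protein genes 12 rose (12 adjusted over the list alone). These 7 lists passed camera at the preset correlation, and none passed with an estimated correlation. The adjusted p with an estimated correlation was 0.134 for cell cycle, 0.225 for the bulge and sebaceous lists, 0.325 for the BMP and repair lists, 0.537 for hair germ and 0.834 for ribosomal proteins.

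No other list passed camera in old. The melanocyte niche list had 5 of 17 genes higher and 2 lower (6 and 3 adjusted over the list alone), with Edn2 at 3.58 and Tgfb3 at 1.04, whereas Edn1 (0.94, SE 0.87), Tgfb2 (-1.32) and Wnt10b (0.69) did not pass. Notch genes had 2 of 18 higher, Dtx4 (1.27) and Hes1 (1.25), and 5 lower, with a mean of 0.03 against a downward test. Glycolysis and hypoxia had 7 of 25 higher, such as Hk2 (1.63, SE 0.19), and 2 lower. Wnt genes rose in 5 and fell in 4 of 29 cases (median -0.12, mean 0.47). Hemidesmosome genes split 8 and 8 of 28. Of 11 fibroblast genes 1 rose and 4 fell, of 12 wound genes 2 rose, and of 8 hair shaft genes 1 rose and 1, Krt75, fell by 4.57 (median -0.41, mean 0.39). Trp53 rose by 0.86 (SE 0.17, adjusted p = 0.0018), Col17a1 fell by 1.33 (SE 0.14, adjusted p = 8.7e-06) and the sort gene Krt15 was lower (-1.47, SE 0.16, adjusted p = 1.3e-05), in all 3 libraries each, and Cdkn1a (-0.11), Ptgs2 (-1.15) and Itga6 (0.34) did not pass.

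Over all 16011 tested genes the log2 fold changes of the 2 ages correlated at 0.511, across genes, which are not independent replicates. Of genes higher in early anagen, 933 passed in both ages against 165.8 for independent lists, and of lower genes 664 against 126.7. Only 26 passed in opposite directions, against 292.2. Of the 4003 genes called in young, 88.4% had the same direction in old and 83.3% were smaller there, with a median ratio of old to young log2 fold change of 0.558. Selection in young favours large young values. Of the 2339 genes called in old, 92.2% had the same direction in young, 58.5% were smaller there and the median ratio of young to old was 0.900.

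The next question was how age changed the cells at rest. Igfbp7 and Grem1 were higher and Fn1 was lower in old telogen. Igfbp7, a secreted binding protein, was 47.4 ± 5.6 CPM in old and 11.7 ± 4.6 CPM in young (2.01, SE 0.24, adjusted p = 0.00055), and Grem1, a secreted BMP inhibitor, 645 ± 221 against 227 ± 39 CPM (1.51, SE 0.22, adjusted p = 0.0026). Fn1, which encodes fibronectin (GRCm39 chromosome 1, 71624679 to 71692359), was 3.88 ± 1.0 against 82.5 ± 53 CPM (-4.41, SE 0.49, adjusted p = 0.00042). All 3 old libraries lay beyond all 3 young libraries for each of these. Kitl (0.56, SE 0.26, adjusted p = 0.35), Krt15 (0.41), Cd34 (0.58), Trp53 (-0.39), Cdkn1a (-0.63), Mki67 (-1.19), Ptgs2 (1.58), Edn1 (2.73), Tgfb2 (1.07) and Wnt10b (-0.48) did not pass, nor did Itga6 or Shh, which had 2 counts in young and 0 in old.

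The count was 330 genes, 165 higher and 165 lower in old, of which 322 had groups that did not overlap, against 10% by chance among unselected genes. It was 97 with the telogen library numbered 1 of both ages left out, a setting added after the data were seen, and 81 of those were among the 330. The highest by the naming rule included Ndufa4l2, a hypoxia-induced mitochondrial protein (2.82, SE 0.50), Ppp1r3b, a glycogen regulator (2.50, SE 0.48), Vit (2.47, SE 0.48) and Lmcd1 (2.41, SE 0.46). The lowest also included Aadacl3 (-4.96, SE 0.83), Edar (-4.85, SE 0.72), Mc5r (-4.79, SE 0.82) and Acoxl (-4.30, SE 1.00). Of the calls named here, Acoxl's was lost without young telogen replicate 1 or 2 or old telogen replicate 2 or 3, Ppp1r3b's without old telogen replicate 1, Vit's without young telogen replicate 2 or old telogen replicate 3, and Lmcd1's without young telogen replicate 1. Over all 38 named genes past the threshold for age in telogen, 17 kept their call with every library left out.

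Of the bulge list 9 of 22 genes were higher in old telogen and 0 lower (17 and 1 adjusted over the list alone), with a median of 0.83. Sfrp1, a Wnt inhibitor (1.43, SE 0.24), Lhx2, a stem cell transcription factor (1.25, SE 0.19), Postn, which encodes periostin (1.19, SE 0.24), and Nfatc1, a quiescence factor (0.99, SE 0.20), led it. Lgr5 (0.84, SE 0.19) and Col17a1 (0.55, SE 0.13), the latter not in that list, were also higher. The calls for Postn, Nfatc1, Lgr5 and Col17a1 were each lost without old telogen replicate 1, and the last 3 also without young telogen replicate 1 or 2. This list kept its call with an estimated correlation (adjusted p = 0.0488 with an estimated correlation). The vessel list did too (3 of 5 genes higher, 3 adjusted over the list alone, adjusted p = 0.0488 with an estimated correlation). Its genes were Flt1, at least 36.2-fold higher in old, Acta2, at 29.2 times the young level (95% counting interval 7.72 to 247), and Cspg4, which these follicle cells made at 330 ± 21 CPM in young and 578 ± 77 CPM in old (0.81, SE 0.13). The Flt1 call was lost without young telogen replicate 1 or 2, and the Acta2 call without young telogen replicate 2 or 3 or old telogen replicate 1 or 2. The other 13 vessel markers reached at most 1.49 CPM in old telogen, the level of Tagln, a smooth muscle gene that was at 0.041 CPM in young telogen.

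Lower in old telogen were 9 of 23 upper follicle and sebaceous genes and 0 higher (10 and 0 adjusted over the list alone), with a median of -0.81. Besides Mc5r, they were led by Far2 (-3.29, SE 0.53), Pparg (-3.09, SE 0.67) and Soat1, which esterifies cholesterol (-2.13, SE 0.48), and camera's adjusted p was 0.0547 with an estimated correlation. Of 32 cell cycle genes 2 were lower, Birc5 (-2.79, SE 0.64) and Tyms (-1.19, SE 0.30), and 12 were lower adjusted over the list alone (adjusted p = 0.467 with an estimated correlation). Both calls were lost without any 1 of 5 telogen libraries, young replicates 1 and 2 and old replicates 1, 2 and 3. Summed over the list, cell cycle genes stood at 1786, 1131 and 521 CPM in the 3 young telogen libraries and at 537 to 872 CPM in the old ones. Of 17 melanocyte niche genes 3 were higher (3 adjusted over the list alone), Sfrp1, Cxcl12, a chemokine (1.03, SE 0.17), and Wnt7b (0.93, SE 0.23), with an adjusted p = 0.0702 with an estimated correlation. The Wnt list had 5 of 29 higher (7 and 1 lower adjusted over the list alone), including Fzd2, a Wnt receptor (1.32, SE 0.18), beside the inhibitors Sfrp1 and Dkk3 (0.86, SE 0.18). Its adjusted p was 0.226 with an estimated correlation. The BMP list had 1 of 33 higher, Grem1, and 2 adjusted over the list alone (adjusted p = 0.261 with an estimated correlation). Glycolysis passed camera with 0 of 25 genes past the gene test (0 adjusted over the list alone, median 0.23, adjusted p = 0.476 with an estimated correlation).

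The other lists did not pass camera for age in telogen. The matrix genes of the hemidesmosome list went both ways, 3 of 28 higher and 4 lower (median 0.05, mean -0.41), with Tnc (-2.62, SE 0.43), Lamb1 (-2.39, SE 0.46) and Fras1 (-2.02, SE 0.49) lower. Of 23 hair germ genes 1 was higher, Cdh3, which encodes P-cadherin (0.84, SE 0.17, lost without young telogen replicate 1 or 2 or old telogen replicate 1), and 1 lower, Edar. Senescence-associated secretory genes had 2 of 18 higher, Igfbp7 and Plau (1.59), and 1 lower, Igfbp2 (-3.53), and epidermal differentiation had 1 of 24 higher, Calml3 (0.88). No gene passed in the p53, prostaglandin, hair shaft, wound, melanocyte, fibroblast, immune, nerve, immediate early, interferon, Notch, repair, mitochondrial or ribosomal protein lists, in each case by edgeR at an adjusted p of 0.05.

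**Figure D2:**
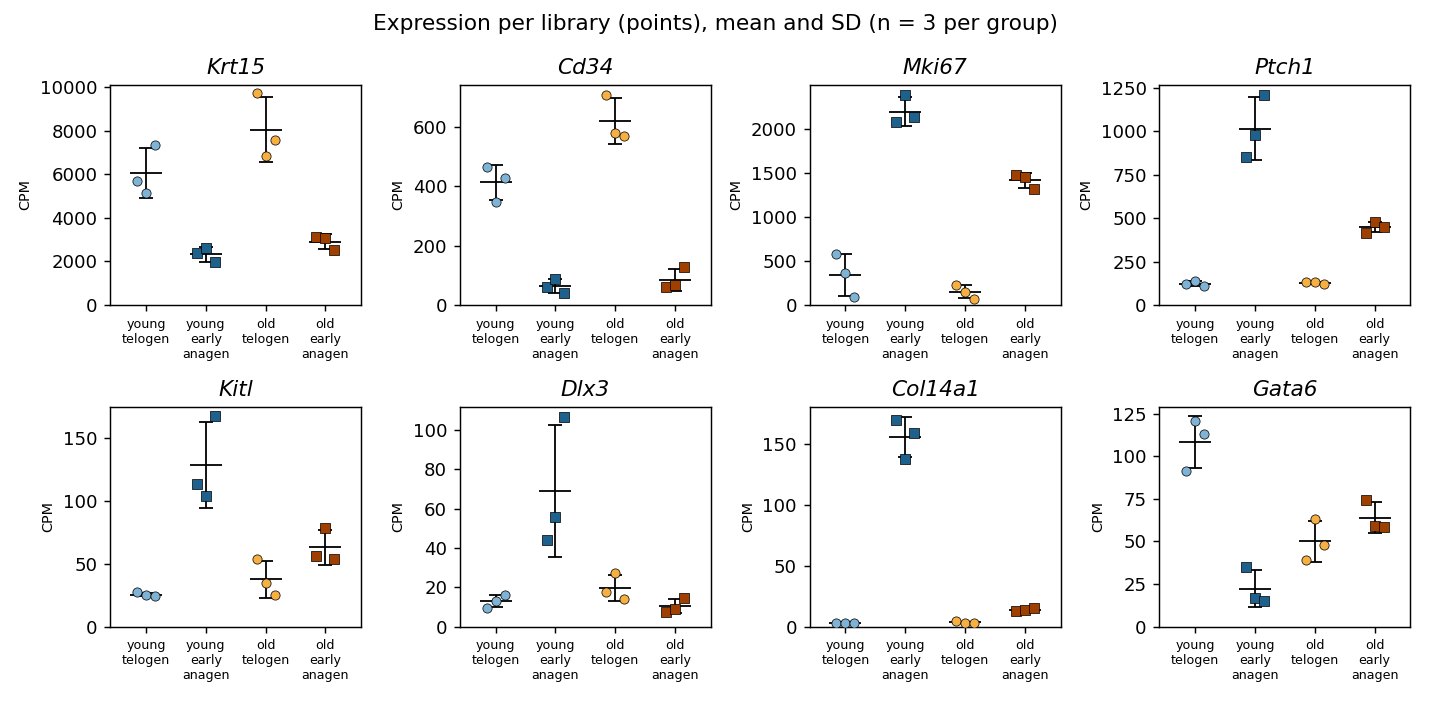
CPM (y axis, linear from 0) of 8 genes in the 12 libraries, with points for libraries and bars for mean and SD (n = 3) in the 4 groups on the x axis. Kitl reached 129 ± 34 CPM in young and 63.2 ± 14 CPM in old early anagen, and Col14a1 reached 155 ± 17 and 14.1 ± 1.5 CPM.

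At the start of hair growth, old cells had less Col14a1, Dlx2, Dlx3 and Kitl than young cells, and more Cxcl12, Grem1 and Gata6. Col14a1, a collagen that associates with fibrils (ENSMUSG00000022371, GRCm39 chromosome 15, 55171146 to 55384199), was 14.1 ± 1.5 CPM in old and 155 ± 17 CPM in young early anagen (-3.46, SE 0.21, adjusted p = 9.9e-08). The homeobox genes Dlx2 (-3.97, SE 0.55) and Dlx3 (-2.71, SE 0.37, 10.5 ± 3.7 against 68.9 ± 33 CPM) and the basement membrane collagens Col4a1 (-2.37, SE 0.28) and Col4a2 (-1.64, SE 0.24) were lower too. Kitl was 63.2 ± 14 CPM in old and 129 ± 34 CPM in young (-1.02, SE 0.25, adjusted p = 0.033), with the 3 old libraries below the 3 young ones. The Kitl call was lost without young early anagen replicate 3 (-0.79, adjusted p = 0.20), at 168 CPM, or old early anagen replicate 1 (adjusted p = 0.14) or 3 (adjusted p = 0.13), and over 13 alternatives its adjusted p ran from 0.00012 to 0.080. Higher in old were Cxcl12, at 157 ± 24 against 42.5 ± 7.4 CPM (1.89, SE 0.18, adjusted p = 5.1e-05), Grem1 (1.54, SE 0.23) and Gata6 (1.52, SE 0.28).

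In all 580 genes passed, 381 higher and 199 lower in old, and all 580 had groups that did not overlap, against 10% by chance among unselected genes. The count was 202 without young early anagen replicate 3, 234, 258 and 307 without old early anagen replicate 1, 2 and 3, and 905 without the telogen libraries numbered 1. The highest by the naming rule were Sncg (4.47, SE 0.64), Bglap3 (3.50, SE 0.86), Slco2b1, an organic anion transporter (2.67, SE 0.37), Skint3 (2.14, SE 0.57) and Sectm1b (2.03, SE 0.46). The lowest, besides Dlx2 and Col14a1, were Basp1 (-3.73, SE 0.80), the histone gene H2bu2 (-3.68, SE 0.92, uncertain) and Peg3, an imprinted zinc finger gene (-2.88, SE 0.33). Vcan was at -4.99 (SE 0.81). The calls for Bglap3, Skint3, Sectm1b, Basp1 and H2bu2 were each lost without young early anagen replicate 3, among other libraries. Over all 49 named genes past the threshold for age in early anagen, 21 kept their call with every library left out.

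Of the hair germ list 8 of 23 genes were lower in old and 0 higher (12 and 0 adjusted over the list alone), with a median of -1.34, including Msx2, a homeobox gene (-2.85, SE 0.59), and Lef1, a mediator of Wnt signalling (-2.53, SE 0.46). The adjusted p was 0.0608 with an estimated correlation. Shh, at 1.498 ± 2.2 CPM in old and 11.97 ± 7.9 CPM in young, did not pass (-2.99, SE 1.10, adjusted p = 0.16). Of the cell cycle list 1 of 32 was lower, Ccnd1 (-0.93, SE 0.22), 5 adjusted over the list alone, with a median of -0.69 and an adjusted p = 0.46 with an estimated correlation. Mki67 did not pass (-0.63, SE 0.42). Of 29 repair genes 1 was lower, Parp1 (-0.89, SE 0.24), and 3 adjusted over the list alone (adjusted p = 0.46 with an estimated correlation). Ccnd1's call was lost without young early anagen replicate 1 or 3 or any old early anagen replicate, and Parp1's without young replicate 2 or 3 or old replicate 1 or 3.

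Higher in old early anagen were 7 of 26 interferon and antigen presentation genes and 0 lower (8 and 1 adjusted over the list alone), with a median of 0.41. H2-K1 (1.32, SE 0.21), Psmb8 (1.30, SE 0.29), Tap2 (1.22, SE 0.26) and B2m (1.13, SE 0.20), all of the class I antigen pathway, led it. H2-K1 was 675 ± 35 CPM in old early anagen, near its telogen levels of 656 ± 41 and 648 ± 23 CPM, and 270 ± 122 CPM in young early anagen. Of the bulge list 4 of 22 were higher, Foxc1 (1.19, SE 0.20), Nfatc1 (1.03, SE 0.20) and Dkk3 (0.94, SE 0.18) among them, and 1 lower, Tbx1 (-0.70, SE 0.16), with 7 and 3 adjusted over the list alone. The sebaceous list had 3 of 23 higher, Gata6, Ly6d (1.32, SE 0.21) and Plet1 (1.13, SE 0.23), and 5 adjusted over the list alone. Glycolysis had 4 of 25 higher (4 adjusted over the list alone), with the glucose transporter Slc2a1 at 1.25 (SE 0.22) and the oxygen sensor Egln3 at 1.44 (SE 0.30). Notch had 2 of 18 higher, Dtx4 (1.42) and Notch3 (1.02), and 5 adjusted over the list alone, and epidermal differentiation 1 of 24, Calml3 (0.86), and 1 adjusted over the list alone. All 6 of these lists passed camera at the preset correlation. The adjusted p with an estimated correlation was 0.46 for the interferon, bulge and glycolysis lists, 0.418 for the sebaceous and Notch lists and 0.496 for epidermal differentiation.

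Among lists that did not pass for age in early anagen, hemidesmosome genes went both ways, 4 of 28 higher and 6 lower (median 0.12, mean -0.38), with Col17a1 at 0.62 (SE 0.13) and Tnc (-2.73, SE 0.42) and Fras1 (-2.56, SE 0.43) at the other end. BMP genes had 4 of 33 higher, including Fst, an activin inhibitor (1.13), and 2 lower, Id3 (-1.85) and Ltbp1 (-1.30). The niche list had 1 of 17 higher, Cxcl12, and 1 lower, Kitl (median 0.14, mean -0.07). Fibroblast genes had 2 of 11 lower, Vcan and Col5a1 (-1.22), Wnt genes 1 of 29 in each direction, Dkk3 and Lef1, prostaglandin genes 1 of 27 higher, Cyp2j6 (1.58), melanocyte genes 1 of 6 higher, Mitf (0.80, SE 0.21), and vessel genes 1 of 5 higher, Flt1, at 81.3 times the young level (95% counting interval 14.2 to 3248). No gene passed in the p53, senescence, hair shaft, wound, immune, nerve, immediate early, mitochondrial or ribosomal protein lists by edgeR. Krt15 (0.32), Itga6 (0.43), Cd34 (0.42), Lgr5 (-0.29), Trp53 (-0.36), Cdkn1a (0.34), Ptgs2 (1.08), Edn1 (-1.62), Tgfb2 (0.39) and Wnt10b (-2.02, SE 1.01) did not pass either.

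**Figure D3:**
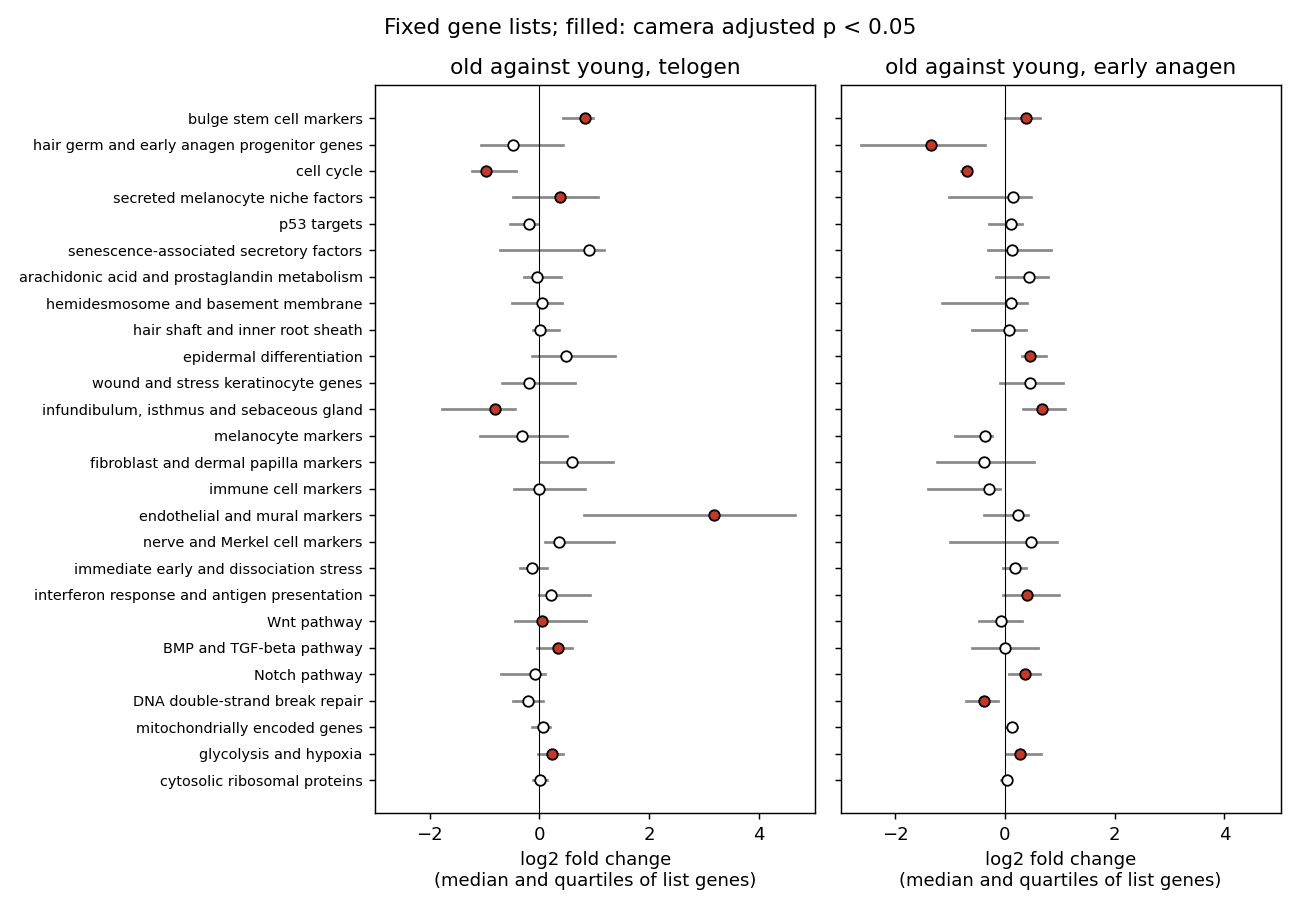
Median (points) and quartiles (lines) of the log2 fold change (x axis) of the genes of each of 26 fixed lists (y axis), old against young, in telogen (left) and early anagen (right), with filled points for lists past camera at the preset correlation. The sebaceous list has a median of -0.81 in telogen and 0.67 in early anagen, and the hair germ list has -0.48 and -1.34.

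Across both stages, 42 genes were higher in old at each stage, against 3.93 for independent lists, and 20 were lower at each, against 2.05. They included Grem1, Cxcl12, Nfatc1 and Col17a1 on the higher side and Fn1, Tnc and Fras1 on the lower. A further 13 genes passed in opposite directions, against 5.98.

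The last comparison asked whether the early anagen response itself differed with age, by testing the old response minus the young response. A higher or lower response is meant with its sign, so that a gene that fell in young alone counts as higher in old. Col14a1 rose less in old, Lhx2 was higher in early anagen than telogen in young and lower in old, and Gata6 fell in young alone. Col14a1 had the lowest adjusted p of the named genes (-3.52, SE 0.31, adjusted p = 2.7e-05): it rose from 3.34 ± 0.11 to 155 ± 17 CPM in young and from 3.49 ± 0.75 to 14.1 ± 1.5 CPM in old. Lhx2 went from 210 ± 32 to 519 ± 136 CPM in young and from 500 ± 92 to 325 ± 46 CPM in old (-1.93, SE 0.27, adjusted p = 0.0027). Gata6 (GRCm39 chromosome 18, 11052064 to 11085635) went from 108 ± 15 to 22.2 ± 11 CPM in young and from 50.01 ± 12 to 63.9 ± 9.1 CPM in old (2.64, SE 0.39, adjusted p = 0.0044). Kitl's response was lower in old by the test (-1.58, SE 0.36, adjusted p = 0.039), a call lost without any 1 of 6 libraries, young telogen replicates 2 and 3, young early anagen replicate 3, old telogen replicate 1 and old early anagen replicates 1 and 3 (adjusted p of 0.053 to 0.11). Over 12 alternatives its adjusted p ran from 3.2e-05 to 0.12.

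**Figure D4:**
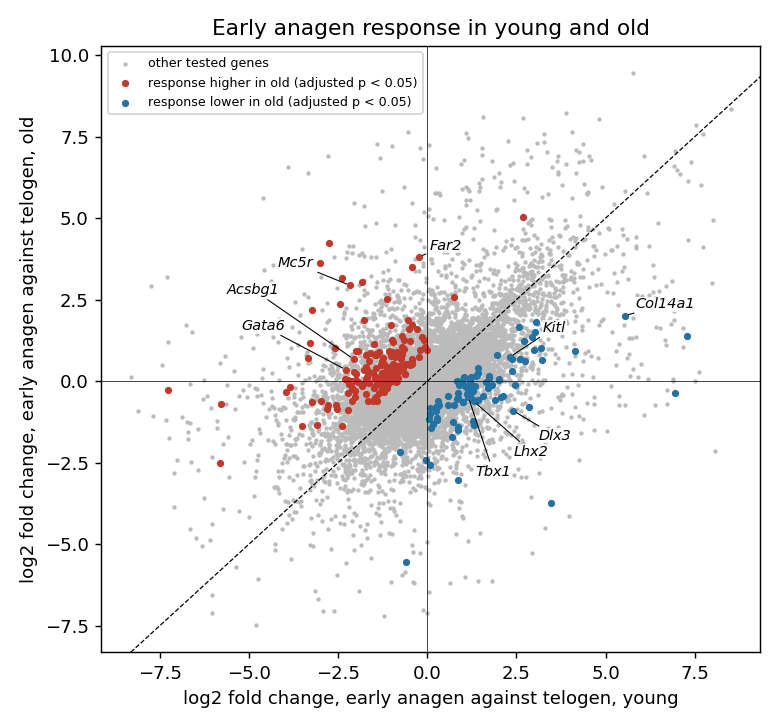
Log2 fold change of early anagen against telogen in young (x axis) and old (y axis) for 16011 genes, with 161 genes whose response was higher in old in red, 89 lower in blue and the diagonal of equal response dashed. Col14a1 and Dlx3 lie below the diagonal, and Gata6, Acsbg1, Far2 and Mc5r lie above it.

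The interaction was called for 250 genes, 161 with a higher and 89 with a lower response in old, and for 249 of them the 3 young and 3 old libraries did not overlap in telogen, in early anagen or in both, which chance gives to 19% of unselected genes if the stages are independent. Leaving out 1 library gave counts of 92 to 396. The lowest by the naming rule, besides Col14a1, were Dlx3 (-3.32, SE 0.51), Dlx2 (-3.22, SE 0.78), Mme, a membrane peptidase (-2.66, SE 0.53), and Plppr3 (-2.58, SE 0.59). The highest were Mc5r (5.10, SE 1.06), Aadacl3 (4.79, SE 1.06), Tgm2, a transglutaminase (4.47, SE 0.76), Aldh1a1, which makes retinoic acid (4.05, SE 0.83), and Far2 (4.04, SE 0.70). Of 34 named genes past the threshold, 8 stayed past it in every alternative and with every library left out: Acsbg1, Gata6, Lama5, Tbx1, Igfbp7, Lhx2, Dlx3 and Col14a1.

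Of the sebaceous list 8 of 23 genes had a higher response in old and 0 a lower one (14 and 0 adjusted over the list alone), with a median of 1.83 and an adjusted p = 0.0481 with an estimated correlation. Acsbg1 was at 2.75 (SE 0.44). Summed, the list went from 6382 ± 1488 to 4389 ± 649 CPM in young and from 4070 ± 1664 to 6973 CPM in old. A changed share of upper follicle or sebaceous cells in the sort was not tested. It cannot be told apart here from a response of the sorted stem cells. Of the hair germ list 6 of 23 were lower (8 lower and 2 higher adjusted over the list alone), including Hoxc13 (-2.48, SE 0.47) and Gli1, the hedgehog effector (-1.51, SE 0.27), with an adjusted p = 0.222 with an estimated correlation. The bulge list had 4 of 22 lower, Lhx2, Tbx1 (-1.64, SE 0.22), Tcf7l1 (-1.64, SE 0.40) and Lgr5 (-1.14, SE 0.27), and 1 higher, Foxc1 (1.32, SE 0.27), with 6 and 1 adjusted over the list alone and an adjusted p = 0.405 with an estimated correlation. Notch had 3 of 18 higher, Dtx4 (2.26), Notch3 (1.76) and Notch1 (0.91), and 4 adjusted over the list alone (adjusted p = 0.222 with an estimated correlation). The BMP list had 2 of 33 lower, Id3 (-2.39) and Smad7 (-1.47), with 6 lower and 2 higher adjusted over the list alone (adjusted p = 0.405 with an estimated correlation). The fibroblast and vessel lists passed camera without any gene past the gene test. Their medians were -1.15 and -2.26, 0 and 2 genes were lower adjusted over the list alone, and the adjusted p was 0.384 and 0.222 with an estimated correlation.

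The other lists did not pass for the interaction. Lama5 (-1.17, SE 0.20), Lamc1 (-1.02, SE 0.23) and Col4a2 (-1.48, SE 0.34) were the 3 of 28 hemidesmosome genes with a lower response in old (list median -0.12, mean 0.03). Single genes passed in the niche list (Kitl), the Wnt list (Fzd2, -1.07), the immediate early list (Egr2, 1.74), and in both directions in the senescence list (Igfbp2, 3.65, and Igfbp7, -1.92) and the interferon list (H2-K1, 1.34, and Gbp2, -2.34). None of the 32 cell cycle genes passed (0 adjusted over the list alone, median 0.22), nor did any of the p53, prostaglandin, hair shaft, epidermal, wound, melanocyte, immune, nerve, repair, mitochondrial, glycolysis or ribosomal protein lists by edgeR. Shh, with 0 counts in old telogen and 2 in young telogen, Mki67 (0.55), Krt15 (-0.09), Cd34 (-0.16), Itga6 (0.44), Col17a1 (0.07), Trp53 (0.03), Cdkn1a (0.96), Ptgs2 (-0.50), Tgfb2 (-0.68), Edn1 (-4.35, SE 1.34, adjusted p = 0.12) and Wnt10b (-1.54) did not pass.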

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

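The tests below on dilution, hair cycle position, sebaceous cells and vessel cells were chosen after the results were seen, and those on Cdh3 and on splits for the age comparisons and the interaction before. The early anagen response differed between ages, by a test of the difference itself, for 250 genes. The genes and lists of the next 2 paragraphs stand here for that reason, with the old response minus the young response in log2. The 3 patterns weighed after them are differences between the ages within a stage.

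Of the named genes, 20 had a negative difference, which holds both genes that rose less in old and genes that fell there. Col14a1 differed by -3.52 (adjusted p = 2.7e-05), Dlx3 by -3.32 (adjusted p = 0.006), Dlx2 by -3.22 (adjusted p = 0.048) and Hoxc13, a homeobox gene of the hair shaft, by -2.48 (adjusted p = 0.013). Lhx2 differed by -1.93 (adjusted p = 0.0027), Tbx1 by -1.64 (adjusted p = 0.0026), Tcf7l1 by -1.64 (adjusted p = 0.048) and Lgr5 by -1.14 (adjusted p = 0.047). Kitl differed by -1.58 (adjusted p = 0.039), Gli1 by -1.51 (adjusted p = 0.009) and Fzd2 by -1.07 (adjusted p = 0.046). Lama5 was at -1.17 (adjusted p = 0.0083), Lamc1 at -1.02 (adjusted p = 0.037) and Col4a2 at -1.48 (adjusted p = 0.038). Id3 was at -2.39 (adjusted p = 0.049), Smad7, an inhibitor of TGF-beta signalling, at -1.47 (adjusted p = 0.033), Igfbp7 at -1.92 (adjusted p = 0.0074) and Gbp2 at -2.34 (adjusted p = 0.045). Mme was at -2.66 (adjusted p = 0.018) and Plppr3 at -2.58 (adjusted p = 0.039).

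A further 14 named genes had a positive difference, which holds both genes that rose in old and genes, such as H2-K1, that fell in young alone. Mc5r differed by 5.10 (adjusted p = 0.023), Aadacl3 by 4.79 (adjusted p = 0.033), Tgm2 by 4.47 (adjusted p = 0.0075), Aldh1a1 by 4.05 (adjusted p = 0.021) and Far2 by 4.04 (adjusted p = 0.0083). Igfbp2 differed by 3.65 (adjusted p = 0.048), Acsbg1 by 2.75 (adjusted p = 0.007) and Gata6 by 2.64 (adjusted p = 0.0044). Dtx4 was at 2.26 (adjusted p = 0.020), Notch3 at 1.76 (adjusted p = 0.028), Notch1 at 0.91 (adjusted p = 0.033), Egr2 at 1.74 (adjusted p = 0.047), H2-K1 at 1.34 (adjusted p = 0.031) and Foxc1 at 1.32 (adjusted p = 0.023). Among lists the median was 1.83 for the upper follicle and sebaceous list, 0.32 for Notch, -0.18 for bulge, -0.93 for hair germ, -1.15 for fibroblast, -2.26 for vessel and -0.38 for BMP genes, and only the sebaceous list passed with an estimated correlation.

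The first pattern weighed is the lower level of Kitl and hair germ genes in old early anagen. Dilution by other cells would lower bulge genes as well. Their median was 0.39 (quartiles 0.01 to 0.64) against -1.34 for the hair germ list, but they were already higher in old telogen (median 0.83). The old response minus the young response had a median of -0.18 for bulge and -0.93 for hair germ genes. These values argue against dilution as the whole source of the pattern, and a partial dilution remains open. The upper follicle and sebaceous list summed to more in old early anagen, at 6973 against 4389 ± 649 CPM. Epidermal differentiation did too, at 4626 against 3202 ± 1110 CPM. The fibroblast list (252 against 377 CPM) and the immune list (66.8 against 78.3 CPM) went the other way. Fewer hair germ cells in the old sort, which the gate of K15-EGFP high, ITGA6 high and Sca-1 negative cells would not exclude, could lower the list. Cdh3, a hair germ marker, was at -0.26 in early anagen (SE 0.17, adjusted p = 0.48), which leaves this open. Cdh3 was already higher in old telogen, so its response, like the median of the hair germ list, was lower in old. A later hair cycle position of the young samples could also lower the hair germ list. The median ratio of old to young response was 0.389 (quartiles -0.30 to 0.62) for the 13 hair germ genes called in young. For 31 cell cycle genes it was 1.05 (quartiles 0.91 to 1.22), and selection in young itself lowers such ratios (0.558 for all 4003 called genes). A median of at least 1 in either list was set to count against this explanation, if counted from a time point that both ages share. In early anagen the summed cell cycle list was also lower in old, at 4373 ± 348 against 7025 ± 274 CPM. It was lower in old telogen too, at 688 ± 170 against 1146 ± 633 CPM, which raises the ratio. An effect of age, itself untested, thus cannot be told apart from hair cycle position without samples staged by histology.

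The second pattern is the lower level of sebaceous and upper follicle genes in old telogen. The gate took Sca-1 negative cells, and Ly6a, the gene of Sca-1, did not exceed 1.66 CPM in any library, which limits but does not exclude upper follicle cells. Fewer infundibulum and isthmus cells in the old sort cannot be told apart from an effect of age, as the median of 7 such genes was -0.67 (-1.11 to -0.21), between the values set for and against it. For fewer mature sebocytes, the median of 9 lipid synthesis genes was -1.48 (-2.55 to 5.63), less steep than Far2 at -3.29, and they were not all lower. Both sets of genes belong to the list in which the pattern was seen, so neither median gives separate evidence. Fewer sebocytes and an effect of age could both hold, untested.

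The third pattern is the higher level of Flt1 and Acta2 in old telogen. Vessel or mural cells, which the gate should exclude, would bring their other markers with them, and the median of 14 other markers in old telogen was 0.307 CPM. That is well under Flt1 at 4.47 CPM and Acta2 at 2.46 CPM and argues against many such cells. A few cells remain open, since Pecam1 was at 0.510 CPM in old telogen against 0.043 CPM in young telogen, Tagln at 1.49 against 0.041 CPM and Myh11 at 0.468 against 0 CPM. Age remains open as an explanation of both, untested.

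The counts of genes were also compared with other splits of the same libraries. For the interaction, 1 of 100 drawn splits, the real one, reached 250 genes, and the highest other reached 29. The other splits mix young and old libraries, whose differences within a stage add spread and lower the number of calls. They therefore cannot exclude chance as a source of the count. For the other comparisons 10 splits are too few to give a share under 0.05. In each, 1 split, the real one, reached the count, with 4003 genes against 0 at most for young, 2339 against 0 for old, 330 against 33 for age in telogen and 580 against 1 for age in early anagen.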

How the results depend on the processing

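The setting that left out both telogen libraries numbered 1 was chosen after the results were seen, and all other settings before. Of 101, 90, 38, 49 and 34 named genes past the threshold in young, old, telogen, early anagen and the interaction, 73, 57, 10, 21 and 8 stayed past it in every setting and with every library left out. Except where construction shows it (a stricter threshold, fewer libraries or other genes tested), the cause of a change was not tested. Whether replicate numbers pair samples is not settled. Deviations of libraries with the same number correlated at -0.0437 to 0.108, with 2 of 18 pairs over 0.1. Those of libraries with different numbers correlated at -0.0917 to 0.0559. Of 12 libraries, 6 matched their own number best, and a block for the number gave 3958, 2329, 321, 628 and 310 genes. At these depths a gene with 0 counts in a group can only be given a lower bound.

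With a 2-fold threshold the counts were 2409 in young, 1393 in old and 317 for age in early anagen. Without a filter they were 854 for age in telogen, 1222 in early anagen and 818 for the interaction, and with DESeq2 683, 1071 and 604. In young, limma split the calls into 2334 higher and 1572 lower on log2(FPKM + 1) and 2242 and 1528 on log2(FPKM + 0.1), against 2010 and 1993 by edgeR. With only the compared groups fitted, early anagen gave 1330 (662 higher, 668 lower). In telogen and the interaction, limma gave 139 and 70 on log2(FPKM + 1), 121 and 52 on log2(FPKM + 0.1), 189 (116 higher, 73 lower) and 61 after quantile normalization, 160 (97 higher, 63 lower) and 73 with median-of-ratios factors, and 115 and 120 with array weights. For early anagen log2(FPKM + 0.1) gave 296. Without the telogen libraries numbered 1, telogen gave 97 and early anagen 905. Leaving out 1 library gave 1526 to 2042 in old, 154 to 442 in telogen, 202 to 568 in early anagen and 92 to 396 for the interaction. Lists past camera with an estimated correlation numbered 0 in young, 0 in old, 2 in telogen, 0 in early anagen and 1 for the interaction. Lists past fry numbered 7 in young, 8 in old, 4 in telogen, 2 in early anagen and 3 for the interaction. Camera at the preset correlation passed 5, 7, 8, 9 and 7. At the preset correlation, telogen had 5 lists without a filter, against 8 with it. The interaction had 11 with array weights, against 7 by edgeR, 4 without the telogen libraries numbered 1 and 4 to 9 with 1 library left out.

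Values that changed sign were those of genes not past the test, besides mt-Cytb (0.0064) and mt-Co1 (0.022) in young after quantile normalization. With array weights Itga6 was 0.050 in young and 0.0089 in telogen, and Col17a1 -0.043 in the interaction. Itga6 in telogen was 0.0015 with mean FPKM of at least 5 and 0.0044 with the block. On log2(FPKM + 1) Cdkn1a in old was 0.021 and Trp53 in the interaction -0.031, and on log2(FPKM + 0.1) they were 0.032 and -0.019, with Ptgs2 in young at 0.10. With median-of-ratios factors Trp53 was -0.018. Without the telogen libraries numbered 1, Itga6 was 0.012 in young and 0.044 in telogen, and in the interaction Krt15 was 0.12, Shh 0.19 and Wnt10b 0.18. With 1 library left out, Itga6 ran from -0.20 to 0.037 in young and -0.076 to 0.11 in telogen, Cdkn1a in old from -0.43 to 0.14 and Wnt10b in telogen from -2.50 to 0.10. In the interaction the ranges were -0.043 to 1.00 for Mki67, -0.031 to 0.22 for Col17a1, -0.093 to 0.12 for Trp53, -0.25 to 0.066 for Krt15, -0.56 to 0.17 for Cd34, -2.99 to 0.22 for Shh, -1.21 to 0.083 for Ptgs2 and -2.12 to 0.48 for Wnt10b.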

Other observations

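The gene groups in this part were chosen after the results were seen, from 1117 Gene Ontology terms, of which 0 passed with an estimated correlation in any comparison. Adh7, an alcohol dehydrogenase that oxidizes retinol, went from 141 ± 22 CPM in young telogen to 50.6 ± 17 CPM in young early anagen, and was 143 ± 31 and 154 ± 24 CPM in the old groups (interaction 1.58, SE 0.32, adjusted p = 0.020). Aldh1a7 was 46.7 ± 15 CPM in young telogen and 5.34 ± 2.1 CPM in old telogen (-3.13, SE 0.57, adjusted p = 0.0073). Of 12 genes of retinol metabolism, 3 had a positive interaction, among them Sdr16c5, a retinol dehydrogenase (2.26, SE 0.44), and 0 a negative one (adjusted p = 0.637 with an estimated correlation). Of 14 genes of long-chain fatty acid metabolism, 7 fell and 0 rose in young early anagen, and 3 had a positive interaction, including Acsl4, an acyl-CoA synthetase (1.65, SE 0.29, adjusted p = 0.0088), with an adjusted p = 0.344 with an estimated correlation. Acsl4 went from 194 ± 30 to 103 ± 36 CPM in young and from 146 ± 9.9 to 243 ± 36 CPM in old.

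Hoxb8, which marks position along the body, went from 8.77 ± 3.5 to 58.5 ± 7.9 CPM in young and from 23.1 ± 3.4 to 35.2 ± 6.6 CPM in old, higher in old at telogen (1.40, SE 0.28, adjusted p = 0.014) and lower in response (-2.13, SE 0.39, adjusted p = 0.011). Hoxa7 was 106 ± 16 against 42.8 ± 15 CPM in telogen (1.31, SE 0.21, adjusted p = 0.0039). Of 66 genes of anterior and posterior patterning, 6 were higher and 0 lower in old telogen, with an adjusted p = 0.716 with an estimated correlation. Of 55 nucleosome assembly genes, 33 rose and 2 fell in young early anagen and 0 were higher and 7 lower in old early anagen than in young, such as H1f5, a linker histone (-1.54, SE 0.30, adjusted p = 0.0086). The adjusted p was 0.283 and 0.407 with an estimated correlation, and histone copies may share reads. Genes higher in old at both stages also included Slitrk5, a neuronal membrane protein (1.78 in telogen, 1.87 in early anagen), Thbs2, which encodes a thrombospondin (1.15 and 1.56), and S100a4, a calcium-binding protein (1.63 and 1.88). Nrp2, a semaphorin receptor (-2.41 and -1.79), Slc7a5, an amino acid transporter (-2.04 and -1.08), and Fgfr2, a growth factor receptor (-0.68 and -1.15), were lower at both.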
